A study of Mus musculus with 19 samples.

How the data were processed

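The measurements are RNA-seq of 19 libraries in 7 groups of primary mouse ventral midbrain cultures. Per the labels' protocols, the 11 lentivirus libraries came from unsorted cultures and were made with SMARTer Ultra Low and Nextera XT kits, and the bexarotene, DMSO, scrambled and shNurr1 libraries came from cells sorted for GFP and were made with Smart-Seq2. Groups were taken from the sample titles and labels alone.

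The lentivirus tables hold RPKM values per gene by the authors, with a base mean signal, a log2 fold change with its standard error and a p-value per gene that the authors deposited from DESeq2, per the file headers. The bexarotene table holds deposited RPKM and raw read counts by the authors, and a further deposited table by DESeq holds base mean signals, the fold as a ratio, its log2 and p-values for genes with adjusted p under 0.05 only. The shNurr1 table holds RPKM and raw counts made with rpkmforgenes on uniquely mapped reads of a STAR alignment to mm10 and the refGene annotation, per the file headers, with lengths corrected for mappability. The submitters' processing notes name Bowtie 0.12.7, DESeq, DESeq2 and mm9 without roles, which does not match that header, so the alignment behind the other tables is not known here.

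The tables hold 23050, 23050 and 23827 rows (lentivirus, bexarotene, shNurr1). Of these, 92 spike-in rows were left out of the lentivirus and bexarotene tables. Rows that repeat a symbol (547 in the bexarotene and 478 in the shNurr1 table) were kept as rows of their own, and 25 symbols that had been turned into dates in the lentivirus tables were kept in the tests as they stand. RFP values were identical in the 2 lentivirus tables, so synuclein and synuclein plus Nurr1 were also compared directly. The lentivirus tables hold no counts. Reads were implied from the steps of the RPKM values in each library, and checked against the authors' base means: over 9855 genes the median ratio was 0.998, and 96.7% lay within 5%. Depth is given in the report.

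The tests, gene lists, rule for named genes and main alternatives were fixed before the data were examined. For the lentivirus comparisons, log2(RPKM + 1) of genes with a mean of at least 1 RPKM was tested with limma 3.58.1 with an expression trend. For bexarotene the counts were tested with edgeR 4.0.16 by the quasi-likelihood test with TMM scaling and its default expression filter. Adjustment was by Benjamini-Hochberg at 0.05. The plan named edgeR for counts and limma for RPKM, so the tests differ by table. For shNurr1 against scrambled no test was made: folds are given with exact 95% intervals from counts. Where a library had no read, the end of the interval nearest to no change is given. The labels do not state that replicates were separate cultures.

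Gene lists, 21 in all, were tested with camera from limma at a preset correlation of 0.01 where at least 5 members were tested, with an estimated correlation and fry beside it: dopamine neuron identity, Ret and GDNF-family signalling, oxidative phosphorylation, mitochondrial ribosome, cytosolic ribosome, proteasome, LXR targets, retinoic acid receptor targets, PPAR targets, cholesterol synthesis, unfolded protein response, p53 targets, interferon response, immediate early genes, pan-neuronal genes, other neuron types, and astrocyte, oligodendrocyte lineage, microglia, mesenchymal and vascular, and cycling progenitor markers. For shNurr1 the median of a list was ranked among 10000 random lists of the same size matched on mean expression.

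Named genes were Nr4a2, Pitx3, Th, Ddc, Slc6a3, Slc18a2, Ret and Gfra1 in every comparison (a further gene of this panel is not reported here); the 8 largest rises and falls among genes past the threshold with non-overlapping groups and at least 5 RPKM in the higher group, without predicted, Riken, microRNA and snoRNA symbols; up to 4 members with the smallest p of each list past the threshold; and for shNurr1 the 10 largest rises and falls among genes with at least 10 RPKM in one library. The 4 tests were tested on simulated data with 200 changed genes: of genes changed 2-fold, 91.0%, 95.5%, 94.0% and 98.5% were recovered (synuclein, synuclein plus Nurr1, the direct comparison, bexarotene), with 3, 2, 8 and 8 false calls.

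Relations between comparisons that share libraries were set beside 100 simulations without effect, drawn with each gene's SD per group. The length trend was a loess fit (span 0.5) on length and mean level. Transcript length was not taken from an annotation but implied by read counts and RPKM values. It may therefore be cut by a correction for mappability. For the lentivirus comparisons the lengths from the bexarotene data served. Alternatives were filters, quantile normalization or DESeq2 1.42.0, pseudocounts, limma without trend, library weights, a replicate block, leaving out each library, RFP1 or RFP2 alone, and one fit of all 11 lentivirus libraries. Added later were edgeR on implied reads, thinning to equal depth, lists without Nr4a2, against each RFP set, without the length trend and without bexarotene replicate 1. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.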

Results

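The data set holds 19 mouse RNA-seq libraries in 7 groups, all from primary ventral midbrain cultures of Pitx3-eGFP embryos, in which green fluorescent protein marks cells that express Pitx3, a transcription factor of midbrain dopamine neurons. The series asks how Nurr1 (gene Nr4a2), a nuclear receptor needed for dopamine neuron development, and ligands of its partner, the retinoid X receptor, act on Ret signalling and on gene expression disturbed by α-synuclein, the main protein of Lewy bodies. In 11 libraries, unsorted E13.5 cultures had been infected with lentivirus for 5 days. These are 5 RFP libraries with a virus for red fluorescent protein, 3 synuclein libraries with α-synuclein and control virus, and 3 synuclein plus Nurr1 libraries. In 6 libraries, E13.5 cultures had been given 100 nM bexarotene, a retinoid X receptor agonist, or its solvent DMSO for 24 hours (3 libraries each) and sorted for GFP. The last pair came from E11.5 cultures infected for 48 hours with a scrambled or a Nurr1 short hairpin virus (shNurr1) and sorted for GFP, 1 library each. The RFP libraries carry 2 titles, RFP1 (3 libraries) and RFP2 (2 libraries), whose meaning the labels do not give. The titles of the synuclein and synuclein plus Nurr1 libraries also hold the word HIGH, which the labels do not explain. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

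Depth differed between the groups. Reads on genes came to 1.95 to 8.49 M in the RFP libraries, 10.5 to 12.8 M with synuclein and 8.82 to 12.3 M with synuclein plus Nurr1, as implied by the steps of the RPKM values. Summed counts were 10.9 to 11.7 M with DMSO, 12.1 to 13.2 M with bexarotene, 5.40 M for scrambled and 7.34 M for shNurr1. No 2 libraries of a group were identical or within sampling noise of each other, but some were close to it. The chi-square per gene, which grows with differences beyond sampling noise, was 1.16 to 1.44 between DMSO libraries. It was 1.24 to 1.37 between synuclein plus Nurr1 libraries and reached 8.92 between an RFP1 and an RFP2 library.

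The first comparison asks what α-synuclein overexpression did to the cultures. The synuclein cultures carried α-synuclein and control virus, and the RFP cultures a virus for red fluorescent protein. Differences in virus dose between them were not tested. Dopamine neuron genes, cholesterol synthesis genes, astrocyte markers and cycling progenitor markers were lower with synuclein than with RFP, and genes of the unfolded protein response and the p53 pathway were higher. With an estimated correlation only the calls of cholesterol synthesis and astrocyte markers held (camera adjusted p = 0.0055 and 0.014), and those of dopamine neuron genes (0.051), cycling progenitor markers (0.051), the unfolded protein response (0.135) and the p53 pathway (0.121) were lost. Slc6a3, the dopamine transporter, fell 4.04-fold on the log2(RPKM + 1) scale, from 59.6 ± 5.36 RPKM with RFP to 14.0 ± 0.323 with synuclein (mean ± SD, n = 5 RFP and 3 synuclein libraries here and in what follows; limma with Benjamini-Hochberg adjustment, adjusted p = 4.7e-06). Th, the rate-limiting enzyme of dopamine synthesis, fell from 55.1 ± 3.97 to 26.9 ± 2.00 RPKM (limma adjusted p = 4.7e-05). Of 11982 genes tested, 3070 rose and 1185 fell, 188 and 91 of them by at least 1 on the log2 scale.

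Because the median of all tested genes moved by 0.13 log2 units, changes against RFP are given below relative to that median, on the same scale, which understates the change of low genes. The p-values beside relative changes, here and in later comparisons, test the change before that shift was taken off.

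In the panel of dopamine neuron genes, Nr4a2 fell from 13.0 ± 1.64 to 4.75 ± 0.565 RPKM (relative log2 change -1.41; limma adjusted p = 9.4e-05). Slc18a2, the vesicular monoamine transporter, fell from 37.9 ± 3.19 to 23.4 ± 1.55 (-0.80; limma adjusted p = 4.6e-04). Ret, the receptor tyrosine kinase for GDNF-family ligands, fell from 5.13 ± 0.622 to 2.83 ± 0.126 (-0.80; limma adjusted p = 0.0015). Ddc, aromatic amino acid decarboxylase, fell from 31.1 ± 4.38 to 23.2 ± 1.32 (-0.53; limma adjusted p = 0.021), a call that was lost without synuclein replicate 2 or replicate 3. Gfra1, the GDNF co-receptor, stood at 14.3 ± 1.74 and 12.6 ± 0.328 RPKM and did not pass (limma adjusted p = 0.227). Pitx3 was at 0 in 8 of the 11 lentivirus libraries, with 1 read in each of the other 3, and was not tested there. Of 20 dopamine neuron genes tested, 9 fell, 2 rose and 9 did not pass (camera adjusted p = 4.3e-06; adjusted p = 0.051 with an estimated correlation). The retinaldehyde dehydrogenase gene Aldh1a1, another member, fell from 29.8 ± 2.90 to 13.47 ± 0.905. Ret and GDNF-family signalling had 5 members higher, 4 lower and 9 not past, with no set call (camera adjusted p = 0.336), and after quantile normalization 2 were higher and 4 lower.

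**Figure D1:**
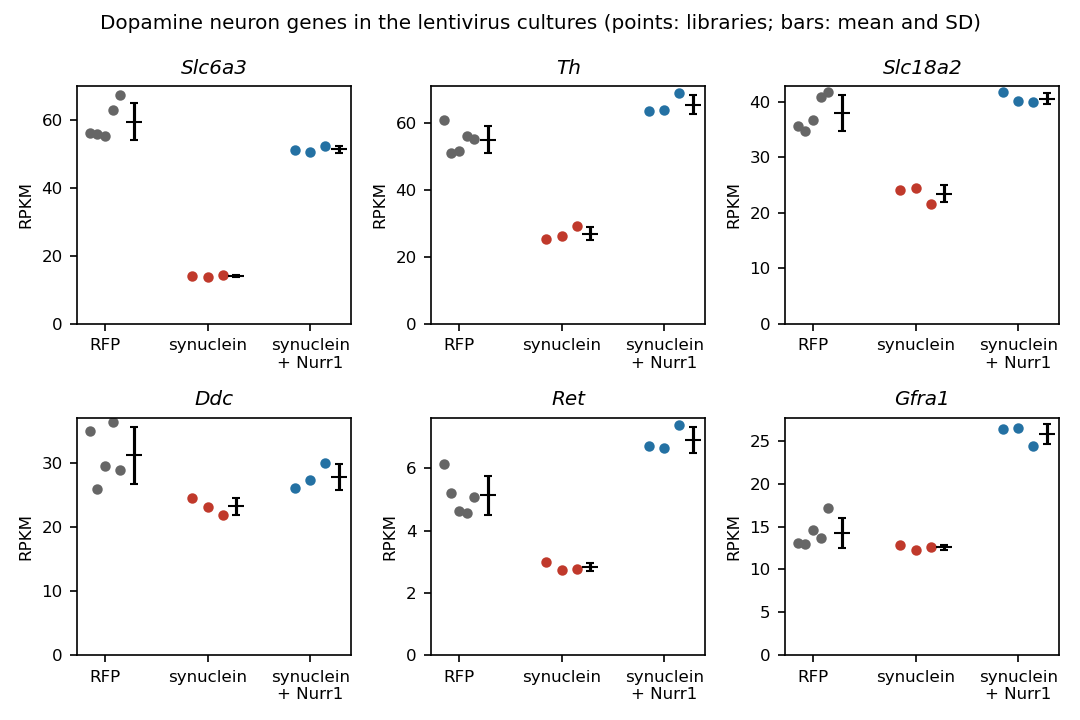
RPKM of Slc6a3, Th, Slc18a2, Ddc, Ret and Gfra1 in the lentivirus cultures (points, libraries; bars, mean and SD). Slc6a3 stands at 59.6 RPKM with RFP, 14.0 with synuclein and 51.3 with synuclein plus Nurr1.

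Cholesterol synthesis was the list with the most uniform change. Of 23 members, 20 fell, none rose and 3 did not pass (camera adjusted p = 1.2e-16; adjusted p = 0.0055 with an estimated correlation). The sterol cyclase Lss changed by -1.54 relative to the median and Insig1, a sterol-responsive regulator, from 74.9 ± 4.69 to 32.9 ± 1.70 RPKM (-1.29). The sterol oxidase Sc4mol went from 587 ± 37.7 to 339 ± 8.81 (-0.92) and Nsdhl from 198 ± 9.81 to 121 ± 0.436 (-0.83). For these genes the limma adjusted p lay between 6.0e-06 and 6.9e-05.

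Markers of other cell types moved too. Of 12 astrocyte markers, 8 fell and 2 rose (camera adjusted p = 8.1e-07; adjusted p = 0.014 with an estimated correlation). Aldoc fell from 412 ± 45.1 to 165 ± 3.97 RPKM, with 1 RFP library apart at 490.4. Slc1a3, a glutamate transporter, fell from 212 ± 22.9 to 95.1 ± 1.58, and Agt from 9.11 ± 0.979 to 2.42 ± 0.133. Of 15 cycling progenitor markers, 9 fell and none rose (camera adjusted p = 2.6e-07; adjusted p = 0.051 with an estimated correlation). Ccnb1, cyclin B1, went from 43.2 ± 4.16 to 8.72 ± 1.02, Top2a, topoisomerase 2α, from 21.97 ± 3.86 to 4.06 ± 0.515, and Cdk1 from 16.7 ± 2.20 to 4.94 ± 0.470. Of 6 oligodendrocyte lineage markers, Pdgfra (3.88 ± 1.23 to 0.187 ± 0.0396) and Olig1 (1.502 ± 0.328 to 0.577 ± 0.140) fell, and the other 4 did not pass (camera adjusted p = 0.015; adjusted p = 0.121 with an estimated correlation). Olig1 was not past the threshold once the libraries were thinned to equal depth. Of 17 pan-neuronal genes, 6 fell, among them Syn2 (21.8 ± 2.46 to 11.1 ± 0.774). The 4 that rose include the neurofilaments Nefm (19.2 ± 1.06 to 33.0 ± 1.13) and Nefl (92.3 ± 6.45 to 137 ± 3.86). The set was called lower (camera adjusted p = 0.037; adjusted p = 0.293 with an estimated correlation). Against RFP2 libraries alone the calls of pan-neuronal genes (camera adjusted p = 0.098) and of the oligodendrocyte lineage (camera adjusted p = 0.082) were lost. With a trend on transcript length removed the pan-neuronal call was lost too (camera adjusted p = 0.363), and mesenchymal and vascular markers were called lower (camera adjusted p = 0.049).

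Of 21 unfolded protein response genes 12 rose, none fell and 9 did not pass (13 rose adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.135 with an estimated correlation). Hspa5, the endoplasmic reticulum chaperone BiP, rose from 268.5 ± 15.6 to 472 ± 0.691 RPKM (0.68). Atf4 rose from 79.7 ± 4.10 to 127.5 ± 1.17 (0.54) and Creld2 from 15.8 ± 2.59 to 25.8 ± 1.58 (0.56), the last not at equal depth. Of 15 p53 target genes 9 rose, 1 fell and 5 did not pass (camera adjusted p = 0.024; adjusted p = 0.121 with an estimated correlation). Among them were Cdkn1a, which encodes the cell cycle inhibitor p21 (84.1 ± 4.57 to 162.5 ± 8.46), and the apoptosis gene Bax (67.9 ± 14.3 to 156.5 ± 9.14). Against RFP2 libraries alone the p53 call was lost (camera adjusted p = 0.147). After quantile normalization 7 unfolded protein response genes rose.

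Subunits of large complexes were called higher as sets against all 5 RFP libraries. Of all 11982 genes tested, 3070 were higher and 1185 lower, so the counts of these sets are to be read against that balance. The counts were 23 higher and 1 lower of 77 oxidative phosphorylation subunits (camera adjusted p = 0.015; adjusted p = 0.626 with an estimated correlation) and 35 and 2 of 76 mitochondrial ribosome genes (camera adjusted p = 0.0030). They were 21 and 2 of 77 cytosolic ribosome genes (camera adjusted p = 0.042) and 14 and 0 of 37 proteasome genes (camera adjusted p = 0.011; 17 higher adjusted over the list alone). For the last 3 sets adjusted p = 0.511 with an estimated correlation. Adjusted over the list alone, 22 oxidative phosphorylation and 20 cytosolic ribosome genes were higher. Examples are Cox6a1 (293 ± 23.8 to 525 ± 11.9 RPKM), Cyc1 (44.4 ± 4.97 to 83.0 ± 2.47, with 1 RFP library apart at 52.9), Mrpl54 (36.4 ± 3.57 to 65.9 ± 2.19), Rps3 (262 ± 27.5 to 383 ± 11.3) and Psmc3 (153 ± 15.3 to 239 ± 12.9). The same 4 sets were lower in RFP2 than in RFP1 libraries, by medians of -0.36, -0.28, -0.28 and -0.26. Against RFP1 libraries alone the calls for oxidative phosphorylation (camera adjusted p = 0.486), the mitochondrial ribosome (0.060) and the cytosolic ribosome (0.407) were lost, and against RFP2 libraries alone all 4 held. After quantile normalization 21 mitochondrial ribosome genes rose and 5 fell. Change also went with transcript length (Spearman's rho -0.265). With a smooth trend on length and mean level removed, all 4 calls were lost (camera adjusted p = 0.647, 0.603, 0.641 and 0.254) and the medians were 0.00, 0.04, -0.08 and 0.07, in place of 0.11, 0.18, 0.14 and 0.11 relative to all tested genes.

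The largest rises were in genes at low levels in the RFP cultures. Vip, vasoactive intestinal peptide, rose from 3.34 ± 1.05 to 19.7 ± 1.49 RPKM. The embryonic globins Hbb-y (7.73 ± 2.76 to 31.9 ± 3.15, with 1 RFP library apart at 2.91) and Hba-x (1.62 ± 0.462 to 8.23 ± 0.726) rose too. So did the Wnt inhibitor Wif1 (3.64 ± 0.657 to 15.4 ± 0.216) and Car13 (1.47 ± 0.392 to 7.69 ± 0.675). Further rises were in Gcg (11.9 ± 2.18 to 44.0 ± 1.66, with 1 RFP library apart at 8.16) and Adh7 (2.54 ± 0.871 to 10.6 ± 0.433). Moap1 went from 3.86 ± 3.74 to 15.2 ± 2.80 but was listed at 0 in the RFP2 libraries and passed in 11 of 20 settings. Besides Ccnb1, Top2a and Slc6a3, the largest falls were the mitotic genes Pbk (30.2 ± 4.96 to 7.48 ± 0.648), Prc1 (37.3 ± 3.35 to 11.3 ± 0.324) and Nusap1 (11.9 ± 1.55 to 3.16 ± 0.664). Others were the metalloproteinase inhibitor Timp2 (26.7 ± 2.73 to 7.29 ± 0.515) and Prom1 (94.6 ± 14.6 to 28.6 ± 1.16).

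The remaining lists gave no set call. LXR targets, which were called lower against RFP2 alone (camera adjusted p = 0.010), had 3 members higher and 6 lower of 15, retinoic acid receptor targets 1 and 1 of 5, and PPAR targets 6 and 2 of 18. Counts were for interferon response genes 2 and 3 of 16, immediate early genes 4 and 0 of 8, other neuron types 3 and 1 of 6, and mesenchymal and vascular markers 1 and 1 of 7. After quantile normalization they were 1 and 6 for LXR targets, 0 and 1 for retinoic acid receptor targets and 0 and 1 for other neuron types. The 1 microglia marker tested was higher, with too few members for a set test. For Ret and GDNF-family signalling the median was -0.03 relative to all tested genes and 0.10 before that shift was taken off. For mesenchymal and vascular markers the median (0.14) and the mean (-0.09) before the shift had opposite signs.

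The RFP and synuclein values did not overlap in 5120 genes (42.7%, where chance gives 3.57%). The balance of calls depended on scaling: quantile normalization gave 1930 higher and 1924 lower, and edgeR's quasi-likelihood test on the implied reads 2380 and 2716, while the authors' deposited table, made with DESeq2, has 2572 and 2759 of 17903 genes. Without synuclein replicate 1, 2 or 3, limma called 2708, 2514 or 2465 genes in place of 4255, and 6399 against RFP2 alone.

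**Figure D2:**
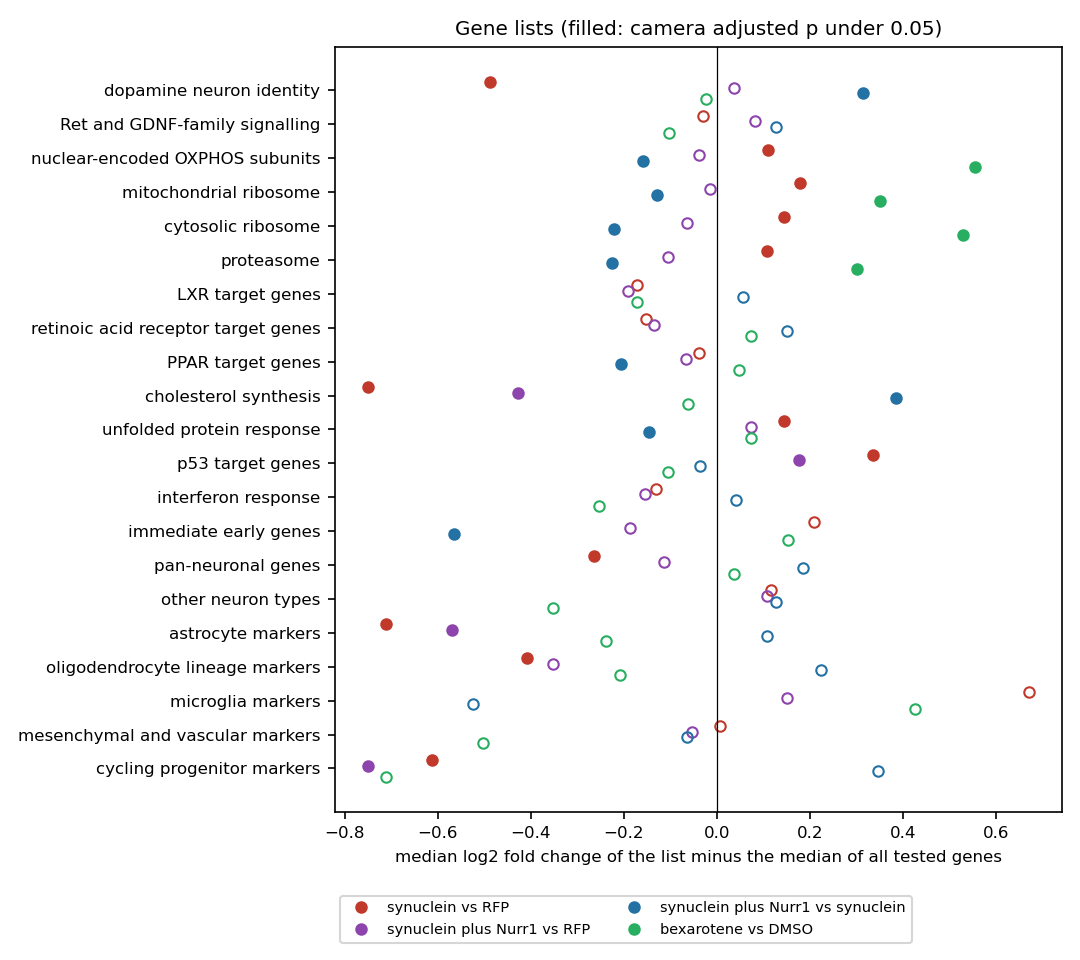
Median log2 change of each gene list relative to the median of all tested genes, filled where the camera adjusted p is under 0.05. Cholesterol synthesis lies at -0.75 with synuclein against RFP and at 0.39 with synuclein plus Nurr1 against synuclein.

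The second comparison asks how cultures with both α-synuclein and Nurr1 virus differed from RFP cultures. Nr4a2 was 74.3 times higher on the log2(RPKM + 1) scale, at 13.0 ± 1.64 RPKM with RFP and 1032 ± 64.4 with synuclein plus Nurr1 (n = 5 and 3; limma adjusted p = 6.6e-10). All 3 libraries carried the Nurr1 signal, with Nr4a2 at 997, 992 and 1106 RPKM. Gfra1 rose from 14.3 ± 1.74 to 25.8 ± 1.19 RPKM (relative log2 change 0.74; limma adjusted p = 3.3e-04), while cholesterol synthesis genes, astrocyte markers and cycling progenitor markers were lower than with RFP. With an estimated correlation the calls of cholesterol synthesis and astrocyte markers held (camera adjusted p = 0.045 for both), and those of cycling progenitor markers (0.063) and p53 targets (0.142) were lost. Of 11932 genes, 2317 rose and 1212 fell, 248 and 73 of them by at least 1 on the log2 scale.

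Ret rose from 5.13 ± 0.622 to 6.93 ± 0.416 RPKM (0.29; limma adjusted p = 0.025, past in 15 of 20 settings). Th rose from 55.1 ± 3.97 to 65.6 ± 2.94 (0.17; limma adjusted p = 0.032, past in 10 of 20 settings). Neither Ret nor Th passed after quantile normalization. Slc6a3 (59.6 ± 5.36 and 51.3 ± 0.937 RPKM), Slc18a2 (37.9 ± 3.19 and 40.6 ± 1.05) and Ddc (31.1 ± 4.38 and 27.8 ± 2.00) did not pass (limma adjusted p = 0.080, 0.389 and 0.353). In other settings Slc6a3 was lower than with RFP and past the threshold in 6 of 20, among them RFP1 alone and RFP2 alone, and its library values did not overlap. Slc18a2 was past in 2 of 20 and Ddc in none. In the dopamine neuron list 7 of 20 members rose and 2 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.597), but after quantile normalization 4 rose and 4 fell. There was no call without Nr4a2, which the virus added, either as measured (camera adjusted p = 0.956) or with the length trend removed (median -0.02; camera adjusted p = 0.920), although the list passed with the trend removed and Nr4a2 kept (camera adjusted p = 0.0012). In Ret and GDNF-family signalling the counts were 6 and 4 of 18 (camera adjusted p = 0.597), or 4 and 4 after quantile normalization.

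In cholesterol synthesis 15 of 23 members fell and 2 rose (camera adjusted p = 7.4e-07; adjusted p = 0.045 with an estimated correlation). Insig1 stood at 37.8 ± 1.97 RPKM against 74.9 ± 4.69, Fdps at 253 ± 8.21 against 374 ± 34.8, where 1 RFP library stood apart at 435, and Dhcr7 at 109 ± 1.96 against 147 ± 5.81. Among 12 astrocyte markers 9 fell and 2 rose (camera adjusted p = 4.3e-05; adjusted p = 0.045 with an estimated correlation). Fabp7, a radial glial fatty acid binding protein, fell from 1564 ± 124 to 772 ± 3.53. Slc1a3 fell from 212 ± 22.9 to 99.7 ± 0.686 and Agt from 9.11 ± 0.979 to 2.35 ± 0.258, while Vim, vimentin, rose from 145 ± 21.96 to 357 ± 10.9. Cycling progenitor markers had 10 of 14 lower and none higher (camera adjusted p = 1.1e-06; adjusted p = 0.063 with an estimated correlation). Ccnb1 stood at 10.9 ± 0.715, Top2a at 7.85 ± 0.220 and Cdk1 at 6.41 ± 0.166 RPKM. In the p53 list 6 of 15 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.036; adjusted p = 0.142 with an estimated correlation). Among them were Ccng1 (40.5 ± 4.24 to 94.4 ± 2.25), Plk2 (82.5 ± 5.05 to 148 ± 1.23) and Aen (13.6 ± 1.88 to 34.3 ± 2.21). Against RFP2 alone this set was not past (camera adjusted p = 0.136).

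The largest rise after Nr4a2 was in Npvf, a neuropeptide precursor, from 2.14 ± 0.483 to 49.6 ± 1.71 RPKM. Then came Fdx1l, which was listed at 0 in all 5 RFP libraries and at 6.81, 6.48 and 4.06 RPKM with synuclein plus Nurr1. It was followed by the annexin gene Anxa10 (10.5 ± 0.822 to 40.4 ± 3.10), Slc38a10 (2.37 ± 0.405 to 10.9 ± 0.426), BC005764 (7.49 ± 0.313 to 28.7 ± 1.12) and Dohh (1.88 ± 0.514 to 8.56 ± 0.932). Tpt1 went from 1.52 ± 1.54 to 5.97 ± 1.70 RPKM and passed in 12 of 19 settings. The largest falls were Scrg1 (12.0 ± 1.12 to 2.43 ± 0.985), Ccnb1, Pbk (30.2 ± 4.96 to 8.73 ± 1.14), Agt, Mmd2 (201 ± 11.8 to 68.4 ± 1.495). Falls also included Cmtm5 (10.9 ± 2.25 to 3.07 ± 0.246), the chromatin protein gene Hmgb2 (7.46 ± 1.72 to 2.01 ± 0.194) and Asrgl1 (56.5 ± 6.00 to 19.8 ± 0.695).

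The complexes that were higher with synuclein had no set call against all 5 RFP libraries: 12 higher and 3 lower of 77 oxidative phosphorylation subunits and 17 and 5 of 76 mitochondrial ribosome genes (camera adjusted p = 0.910 and 0.597). They were 7 and 5 of 76 cytosolic ribosome genes and 6 and 1 of 37 proteasome genes (camera adjusted p = 0.438 and 0.687). After quantile normalization the counts were 15 and 10 for the mitochondrial and 6 and 8 for the cytosolic ribosome. Oxidative phosphorylation was called lower against RFP1 (median before the shift was taken off -0.12; camera adjusted p = 0.0031) and higher against RFP2 (0.26; camera adjusted p = 2.0e-06). The proteasome likewise turned from lower (camera adjusted p = 0.039) to higher (camera adjusted p = 0.029). The cytosolic ribosome was called lower against RFP1 only (camera adjusted p = 0.039) and the mitochondrial ribosome higher against RFP2 only (camera adjusted p = 0.0024). Before the shift of all tested genes was taken off, the proteasome had a median of -0.03 and a mean of 0.05 against all RFP. The medians of the mitochondrial and the cytosolic ribosome relative to all tested genes were -0.02 and -0.06.

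No set call was made for LXR (4 higher and 3 lower of 15, or 1 and 4 after quantile normalization), retinoic acid receptor (1 and 1 of 5) or PPAR targets (2 and 3 of 18). Nor was one made for the unfolded protein response (6 and 1 of 21; 8 and 2 adjusted over the list alone), interferon response (3 and 2 of 16, or 2 and 3 after quantile normalization), immediate early (0 and 2 of 8) and pan-neuronal genes (4 and 4 of 17). Other neuron types (1 and 0 of 6), oligodendrocyte lineage (1 and 2 of 7) and mesenchymal and vascular markers (1 and 2 of 7) had none either, and the 1 microglia marker did not pass. Adjusted over the list alone, the counts were 7 and 4 for Ret and GDNF-family signalling, 12 and 2 for oxidative phosphorylation, 4 and 3 for the cytosolic ribosome and 5 and 1 for the proteasome. They were 4 and 5 for pan-neuronal genes and 1 and 3 for the oligodendrocyte lineage. Before the shift was taken off, PPAR targets had a median of 0.01 and a mean of -0.05. Against RFP2 alone LXR targets were called lower (camera adjusted p = 0.041). Library values did not overlap in 4580 genes (38.4%, chance 3.57%). Quantile normalization gave 1729 higher and 1868 lower, edgeR's quasi-likelihood test on the implied reads 2428 and 2486, and the authors' deposited table has 2466 and 2581 of 17742. The limma count of 3529 became 2059, 2092 or 2091 without synuclein plus Nurr1 replicate 1, 2 or 3, 5863 against RFP1, 5495 against RFP2 and 6165 with library weights.

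The third comparison sets synuclein plus Nurr1 directly against synuclein, and asks what added Nurr1 changed in cultures that carried α-synuclein. Dopamine neuron genes and cholesterol synthesis genes were higher with added Nurr1, and oxidative phosphorylation, ribosome, proteasome, PPAR target and immediate early genes were lower. With an estimated correlation only the call of cholesterol synthesis held (camera adjusted p = 0.044), and the others were lost (camera adjusted p = 0.111 to 0.187). The calls of oxidative phosphorylation and both ribosome sets were also lost once a trend with transcript length was removed. Slc6a3 rose 3.50-fold on the log2(RPKM + 1) scale, from 14.0 ± 0.323 to 51.3 ± 0.937 RPKM (mean ± SD, n = 3 each; limma adjusted p = 3.9e-08). Th rose from 26.9 ± 2.00 to 65.6 ± 2.94 (limma adjusted p = 1.3e-06) and Ret from 2.83 ± 0.126 to 6.93 ± 0.416 (limma adjusted p = 8.4e-06). Gfra1 rose from 12.6 ± 0.328 to 25.8 ± 1.19 (limma adjusted p = 2.1e-06). Of 12099 genes, 2629 rose and 3768 fell, but only 46 and 45 by at least 1 on the log2 scale.

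Nr4a2 itself went from 4.75 ± 0.565 to 1032 ± 64.4 RPKM (limma adjusted p = 8.5e-11), and Slc18a2 rose from 23.4 ± 1.55 to 40.6 ± 1.05 (relative log2 change 0.82; limma adjusted p = 1.0e-05). Ddc rose from 23.2 ± 1.32 to 27.8 ± 2.00 (0.30; limma adjusted p = 0.0082), and did not pass when all 11 lentivirus libraries shared one fit. In the dopamine neuron list 12 of 20 members rose and 5 fell (camera adjusted p = 1.7e-04; adjusted p = 0.111 with an estimated correlation; camera adjusted p = 0.0011 without Nr4a2). Chrna6, a nicotinic receptor subunit, was among them (17.6 ± 0.610 to 35.2 ± 0.849). Ret and GDNF-family signalling had 7 of 19 higher and 5 lower (camera adjusted p = 0.124).

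Of 23 cholesterol synthesis genes, 20 rose and 1 fell (camera adjusted p = 8.2e-09; adjusted p = 0.044 with an estimated correlation). Lss went from 55.8 ± 1.11 to 108 ± 2.42 RPKM, Mvd from 26.1 ± 0.619 to 54.1 ± 1.59 and Acat2 from 325 ± 11.7 to 467 ± 3.08. Lss, Insig1, Fdps and Dhcr7 nevertheless remained below RFP in the second comparison.

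Oxidative phosphorylation subunits fell in 54 of 77 cases and rose in 10 (54 became 55 adjusted over the list alone; camera adjusted p = 2.0e-06; adjusted p = 0.178 with an estimated correlation). Examples are Ndufb9 (513 ± 4.97 to 409 ± 1.62), which was not past the threshold in one fit of all 11 lentivirus libraries, and Ndufa12 (522 ± 27.7 to 382 ± 8.63). Mitochondrial ribosome genes fell in 45 of 76 (camera adjusted p = 1.1e-04; adjusted p = 0.179 with an estimated correlation). Mrpl24 went from 56.5 ± 0.531 to 39.1 ± 1.18. Cytosolic ribosome genes fell in 48 of 77 and rose in 1 (53 lower adjusted over the list alone; camera adjusted p = 2.0e-06; adjusted p = 0.154 with an estimated correlation). Rpl15 went from 140 ± 10.8 to 89.5 ± 2.71. Proteasome genes fell in 27 of 36 (camera adjusted p = 4.5e-07; adjusted p = 0.154 with an estimated correlation). Psmb2 went from 667 ± 7.92 to 494 ± 5.03. PPAR targets fell in 11 of 18 (camera adjusted p = 0.0025; adjusted p = 0.187 with an estimated correlation). The carnitine carrier Slc25a20 went from 61.9 ± 3.09 to 43.0 ± 0.557 and the lipid droplet gene Plin2 from 51.0 ± 1.06 to 37.2 ± 1.54. Mitochondrial ribosome genes rose in 6 cases, proteasome genes in 3 and PPAR targets in 0. Adjusted over the list alone, 46 mitochondrial ribosome, 28 proteasome and 12 PPAR target genes fell. Changes in these sets were small, with medians of -0.13 to -0.22 relative to all tested genes.

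These complexes have short transcripts, and longer transcripts were higher with added Nurr1 (Spearman's rho of the change with length 0.272). With a smooth trend on length and mean level removed, the calls of oxidative phosphorylation, the mitochondrial ribosome and the cytosolic ribosome were lost (camera adjusted p = 0.985, 0.192 and 0.638). Their medians were then -0.04, -0.07 and -0.05, in place of -0.16, -0.13 and -0.22 relative to all tested genes. The proteasome (median -0.14; camera adjusted p = 0.013), PPAR targets (-0.25; camera adjusted p = 0.014), dopamine neuron genes without Nr4a2 (0.34; camera adjusted p = 4.9e-12), cholesterol synthesis (0.36; camera adjusted p = 8.5e-15) and immediate early genes (-0.59; camera adjusted p = 9.3e-06) kept theirs.

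Immediate early genes fell in 7 of 8 (8 adjusted over the list alone; camera adjusted p = 6.0e-04; adjusted p = 0.179 with an estimated correlation). Fos went from 51.7 ± 1.75 to 27.2 ± 0.838 RPKM. Nr4a1, a relative of Nr4a2, went from 6.56 ± 0.374 to 2.85 ± 0.342 and Arc from 3.65 ± 0.667 to 1.47 ± 0.110, the last not at equal depth. In the unfolded protein response 11 of 21 fell and 2 rose (camera adjusted p = 0.034; adjusted p = 0.179 with an estimated correlation and 0.192 with the length trend removed). Calr went from 273 ± 4.62 to 223 ± 3.29 and Creld2 from 25.8 ± 1.58 to 16.5 ± 0.623, the last not past the threshold at equal depth. The chaperone gene Dnajb9 rose from 9.30 ± 0.780 to 13.8 ± 0.363.

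Npvf again led the rises after Nr4a2 (8.12 ± 1.67 to 49.6 ± 1.71 RPKM), with Slc6a3, Vat1l (16.6 ± 0.447 to 49.1 ± 1.31), the transporter Slc10a4 (3.87 ± 0.255 to 12.9 ± 1.31). Others were the calcium-binding protein gene Calb1 (12.6 ± 0.501 to 37.7 ± 0.592), Adam22 (11.9 ± 0.419 to 35.4 ± 1.40) and Timp2 (7.29 ± 0.515 to 20.96 ± 0.873). The largest falls were the nuclear noncoding RNA Malat1 (421 ± 13.48 to 132 ± 2.95), Calcb (9.20 ± 0.380 to 2.51 ± 0.798), Spink10 (7.09 ± 1.22 to 2.19 ± 0.481), Plaur (5.98 ± 0.526 to 1.80 ± 0.462). Falls were also seen in Vip (19.7 ± 1.49 to 7.65 ± 1.16), Hba-x (8.23 ± 0.726 to 3.04 ± 1.00), Iapp (7.05 ± 0.696 to 2.55 ± 0.508) and Gpr83 (10.5 ± 0.237 to 4.06 ± 0.519).

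No set call was made for LXR (7 higher and 6 lower of 16) or retinoic acid receptor targets (1 and 2 of 5). Nor was one made for p53 targets (4 and 7 of 16), interferon response (3 and 3 of 15) and pan-neuronal genes (8 and 5 of 17), although the last were called higher with the length trend removed (camera adjusted p = 0.041). Other neuron types (3 and 2 of 6), astrocyte (5 and 3 of 12), mesenchymal and vascular (2 and 3 of 7) and cycling progenitor markers (7 and 2 of 13) had none. Oligodendrocyte lineage (2 and 0 of 4) and microglia markers (0 and 1 of 1) had too few members for a set test. Before the shift was taken off, the p53 list had a median of -0.08 and a mean of 0.00, and interferon response genes -0.01 and 0.04. Adjusted over the list alone, 12 unfolded protein response genes fell, and the counts were 6 and 3 for astrocyte, 7 and 3 for cycling progenitor, 2 and 1 for oligodendrocyte lineage and 2 and 4 for mesenchymal and vascular markers. Values of the groups did not overlap in 7413 genes (61.3%, chance 10%). The split was 3697 higher and 3370 lower by edgeR's quasi-likelihood test on the implied reads. The limma count of 6397 fell to 2131 when all 11 lentivirus libraries shared one estimate of the spread and to 2337 when all libraries were thinned to the shallowest.

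About as many genes that changed with synuclein went the other way with added Nurr1 as did not, and of those called in both comparisons most went the other way. Of 3070 genes that were higher with synuclein than with RFP, 1634 were lower with added Nurr1 and 437 went further up, where independent lists would share 973. Of 1129 lower genes that were also tested in the direct comparison, 557 were higher and 136 went further down, against 246 by independent lists. These are 53.2% of the higher and 49.3% of the lower genes, or 46.8% and 39.7% with RFP1 alone as the control. Among the genes called in both comparisons, 79.3% went opposite ways, and the figure was 72.8% with RFP1 and 81.3% with RFP2 as the control. The comparisons share the synuclein libraries, which alone gives a negative relation and favours opposite calls, and no value of these percentages without an effect was simulated. The counts also depend on scaling: quantile normalization left 1930 genes higher with synuclein, and opposite calls were not counted on that scale. The covariance of the log2 changes over 11999 genes was -0.0504. Simulations with no effect gave a mean of -0.00519 and a range of -0.00956 to -0.00318. Pearson's r was -0.393, against -0.333 in those simulations. With RFP1 or RFP2 alone as the control the covariance was -0.0404 or -0.0654, against a lowest simulated value of -0.00756 or -0.00857. The covariance beyond what the spread within the shared libraries gives was estimated at -0.0452.

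The changes of synuclein and of synuclein plus Nurr1 against RFP were also related to each other. Both rose in 1547 genes, where independent lists would share 581, and both fell in 660, against 121. Sharing the RFP libraries favours calls in the same direction, which independent lists leave out. These counts also depend on scaling: quantile normalization left 1930 and 1729 genes higher, and shared calls were not counted on that scale. Across 11999 genes, which are not independent replicates, Pearson's r was 0.695 and Spearman's rho 0.686, where simulated unchanged groups gave r of 0.753 through the shared controls alone. The covariance was 0.114 against 0.0167 simulated, a difference of 0.0974, and it was 0.0986 and 0.0735 when RFP1 served one comparison and RFP2 the other.

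The fourth comparison asks what the retinoid X receptor agonist bexarotene did in sorted GFP-positive cells within 24 hours. Genes for oxidative phosphorylation, the mitochondrial and cytosolic ribosome and the proteasome were higher, Th and Pitx3 were higher, and Nr4a2 and Gfra1 were lower, while no difference was detected for Ret. With an estimated correlation only the call of the cytosolic ribosome held (camera adjusted p = 0.027), and those of oxidative phosphorylation (0.075), the mitochondrial ribosome (0.099) and the proteasome (0.099) were lost. With a trend on transcript length removed, however, the cytosolic ribosome median lay at percentile 47.9 of random lists matched on length and level. Th rose from 649 ± 11.4 RPKM with DMSO to 959 ± 36.6 with bexarotene (mean ± SD, n = 3 each; log2 change 0.54 ± 0.03 SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.8e-09). Pitx3 rose from 10.6 ± 0.524 to 17.1 ± 0.705 (0.66 ± 0.08 SE; edgeR adjusted p = 4.8e-06). Of 13191 genes, 4395 rose and 4370 fell, 547 and 778 of them by at least 1 on the log2 scale.

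Gfra1 fell from 180 ± 4.71 to 131 ± 6.28 RPKM (-0.48; edgeR adjusted p = 5.2e-08). Nr4a2 fell from 162 ± 1.55 to 135 ± 8.13 (-0.33; edgeR adjusted p = 7.5e-07). Ret stood at 33.7 ± 0.532 and 34.8 ± 0.777 RPKM, a log2 change of 0.02 with an SE of 0.04 (edgeR adjusted p = 0.616). Slc6a3 (639 ± 5.03 and 662.5 ± 7.53), Slc18a2 (199 ± 3.84 and 193.5 ± 23.5) and Ddc (214 ± 0.553 and 212 ± 6.90) did not pass either (edgeR adjusted p = 0.421, 0.367 and 0.339). Bexarotene replicate 1 stood apart from replicates 3 and 2 (chi-square per gene 5.85 and 4.49, against 1.43 between those 2). Without it Slc18a2 fell (-0.17, edgeR adjusted p = 2.4e-07) and Ddc was called lower too (edgeR adjusted p = 0.043). The dopamine neuron list had 6 of 24 members higher and 8 lower (camera adjusted p = 0.853), and Ret and GDNF-family signalling 5 and 8 of 21 (camera adjusted p = 0.714; median -0.09, mean 0.08).

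Of 75 oxidative phosphorylation subunits 69 rose and 2 fell (70 and 2 adjusted over the list alone; camera adjusted p = 5.0e-21; adjusted p = 0.075 with an estimated correlation). Ndufa4 rose from 335 ± 12.7 to 699 ± 8.96 RPKM, Cox7b from 87.6 ± 3.45 to 187 ± 7.91 and Atp5g3 from 316 ± 1.29 to 533 ± 6.08. Mitochondrial ribosome genes rose in 59 of 76 cases and fell in 2 (camera adjusted p = 2.3e-10; adjusted p = 0.099 with an estimated correlation). Mrpl33 went from 87.3 ± 3.43 to 169 ± 8.53, Mrpl41 from 25.6 ± 1.32 to 48.9 ± 1.26 and, in the other direction, Mrps30 from 7.73 ± 0.481 to 2.09 ± 0.202. Cytosolic ribosome genes rose in 58 of 71 and fell in 0 (camera adjusted p = 3.7e-10; adjusted p = 0.027 with an estimated correlation). Rps14 went from 329 ± 3.10 to 553 ± 33.5 and Rpl32 from 317 ± 18.2 to 519 ± 12.2. Proteasome genes rose in 29 of 37 and fell in 3 (30 and 3 adjusted over the list alone; camera adjusted p = 3.9e-07; adjusted p = 0.099 with an estimated correlation). Psma7 went from 317 ± 14.6 to 507 ± 20.6 and Psmb1 from 241 ± 1.53 to 359 ± 11.1.

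Transcript length went with the direction of change. The median log2 change fell from 0.32 in the shortest class of genes (median length 1013 bases) through 0.10, -0.05 and -0.17 to -0.23 in the longest (5995 bases). Spearman's rho of the change with length was -0.385 across 13191 genes. Members of these lists are short by the lengths that counts and RPKM values imply, which may be cut where reads do not map uniquely. The median lengths were 609 bases for oxidative phosphorylation, 992 for the mitochondrial ribosome, 243 for the cytosolic ribosome and 1252 for the proteasome. With a smooth trend on length and mean level removed, the medians were 0.41, 0.25, 0.24 and 0.13, at percentiles 100, 98.9, 47.9 and 80.4 of random lists matched on both. The camera adjusted p was 1.4e-16, 2.3e-05, 0.028 and 0.052, so that the proteasome call was lost.

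**Figure D3:**
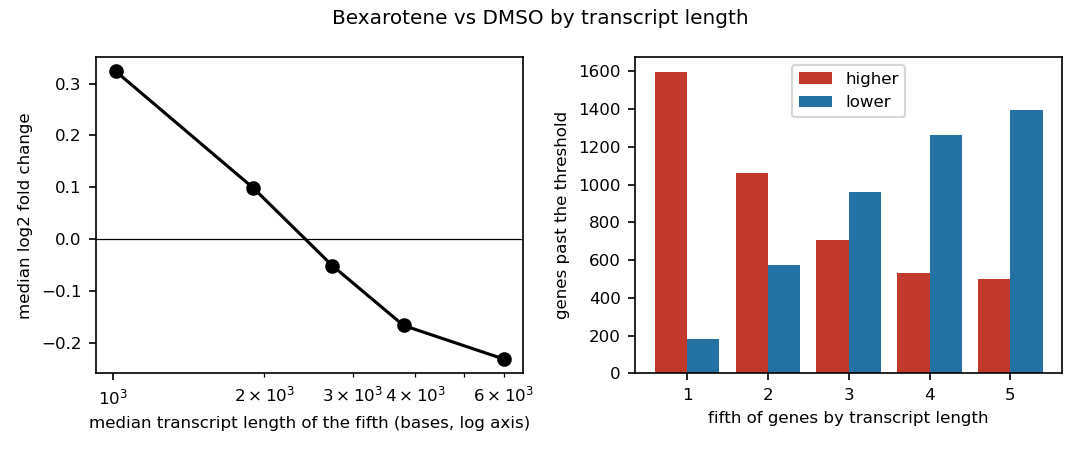
Genes in 5 classes of transcript length, with the median log2 change of bexarotene against DMSO on the left and the numbers higher and lower on the right. In the shortest class 1596 genes rose and 180 fell, and in the longest 500 rose and 1393 fell.

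The largest rises were Cartpt, a neuropeptide precursor (1.28 ± 0.375 to 5.46 ± 1.14 RPKM), Rnaset2b (3.10 ± 1.11 to 12.8 ± 3.94), which has a near-identical copy in the mouse genome, the calcium channel gene Orai3 (1.91 ± 0.165 to 6.56 ± 0.0544). Others were Rasl10b (1.68 ± 0.0749 to 5.77 ± 0.316), Echdc2 (3.42 ± 0.258 to 10.8 ± 1.19), Purg (4.60 ± 0.416 to 14.5 ± 1.06), AI450353 (8.01 ± 0.341 to 24.7 ± 2.77) and Nek8 (2.14 ± 0.181 to 6.58 ± 0.286). The largest falls were the GABA receptor subunit Gabrq (8.55 ± 0.429 to 1.68 ± 0.228), Gal3st3 (30.9 ± 0.394 to 6.78 ± 0.789), Mgst1 (5.84 ± 1.23 to 1.34 ± 0.157). Others were Btd, biotinidase (8.34 ± 0.862 to 2.19 ± 0.152), the endothelin receptor Ednrb (8.79 ± 0.446 to 2.40 ± 0.338), Mrps30, the zinc transporter Slc30a9 (46.1 ± 1.86 to 12.8 ± 0.452) and Trp53inp1 (5.26 ± 0.179 to 1.61 ± 0.328).

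Lists of nuclear receptor targets gave no set call. LXR targets had 5 higher and 6 lower of 14 (camera adjusted p = 0.853). The counts were for retinoic acid receptor targets 4 and 1 of 9 (median 0.08, mean 0.86, camera adjusted p = 0.392). They were 5 and 6 of 16 for PPAR targets (camera adjusted p = 0.888). The same held for cholesterol synthesis (8 and 10 of 24), the unfolded protein response (9 and 4 of 21), p53 targets (5 and 4 of 13). It held for interferon response (4 and 8 of 17), immediate early (4 and 3 of 10) and pan-neuronal genes (6 and 5 of 17; median 0.05, mean -0.02) and other neuron types (0 and 3 of 6). It also held for astrocyte (1 and 6 of 12), oligodendrocyte lineage (2 and 4 of 8), mesenchymal and vascular (1 and 2 of 5) and cycling progenitor markers (2 and 4 of 9). With the length trend removed, astrocyte markers were called lower (median -0.29; camera adjusted p = 0.028). Of 2 microglia markers 1 was higher. Adjusted over the list alone, the counts were 60 and 2 for the mitochondrial ribosome, 8 and 4 for the unfolded protein response, 5 and 3 for immediate early genes and 3 and 4 for cycling progenitor markers. DMSO and bexarotene values did not overlap in 9192 genes (69.7%, chance 10%). The authors' deposited table, made with DESeq, lists 776 higher and 993 lower genes.

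The fifth comparison, of the shNurr1 with the scrambled library, asks what loss of Nurr1 does, and with 1 library per group it has no replicate check and no p-value. Nr4a2, the target, stood at 75.6 RPKM in the scrambled and 63.4 in the shNurr1 library, a ratio of 0.838 (95% exact binomial interval 0.777 to 0.904). The intervals given here cover counting error only. Gfra1 (0.825) and Ddc (0.781) had lower ratios than Nr4a2. The Nr4a2 interval lies below 1, but with 1 library each a loss of Nurr1 RNA cannot be told from a difference between libraries. Th, at 1045 and 453.5 RPKM (ratio 0.434, 0.420 to 0.449), Slc18a2, at 67.4 and 30.7 (0.455, 0.417 to 0.496), and Slc6a3, at 30.4 and 15.5 (0.510, 0.447 to 0.581), were lower in the shNurr1 library. Immediate early genes stood higher there and interferon response and cholesterol synthesis genes lower than expression-matched random lists. Of 6179 genes with at least 10 RPKM in one library, 525 were at least 1 log2 unit higher and 579 lower in the shNurr1 library.

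Other panel genes differed in both directions. Ddc stood at 269 and 210.4 RPKM in the scrambled and shNurr1 library (ratio 0.781, 0.742 to 0.823) and Gfra1 at 63.3 and 52.2 (0.825, 0.759 to 0.897). Ret was higher in the shNurr1 library, at 31.7 and 45.7 RPKM (1.44, 1.35 to 1.55), and so was Pitx3, at 6.46 and 19.3 (2.96, 2.15 to 4.15). In mm10, the build this table's header names, RefSeq gene models place Nr4a2 on chromosome 2 from 57106830 to 57124003, Th on chromosome 7 from 142892779 to 142899995. Slc6a3 lies on chromosome 13 from 73536128 to 73578672, Slc18a2 on chromosome 19 from 59260878 to 59296012. Ddc lies on chromosome 11 from 11814101 to 11898144, Pitx3 on chromosome 19 from 46135281 to 46148325. Ret lies on chromosome 6 from 118151748 to 118197744 and Gfra1 on chromosome 19 from 58235581 to 58455946. Counts are of reads over each gene's exons.

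Immediate early genes had a median log2 difference of 1.76, at percentile 100 of 10000 random lists matched on mean expression, with 8 of 12 members at least 1.5-fold higher and 1 lower. Fos stood at 26.0 and 345 RPKM (ratio 13.3, 11.8 to 15.0) and Nr4a1 at 1.58 and 25.7 (16.3, 10.5 to 26.5). Fosb had no read in the scrambled library and was at least 76.2-fold higher by the lower end of the interval. Cytosolic ribosome (median 0.44, 31 of 77 higher and 2 lower) and oxidative phosphorylation genes (0.39, 21 of 77 higher and 1 lower) were at percentile 100. The p53 targets (6 of 14 higher and 1 lower) and the mitochondrial ribosome (14 of 76 higher and 5 lower) were at 95.02 and 95.9. Cholesterol synthesis had a median of -0.49, below every matched random list, with 11 of 24 members lower and 0 higher. Interferon response genes had -1.40 at percentile 0.07 (9 of 12 lower), pan-neuronal genes -0.40 at 0.55 (4 of 18 lower). Astrocyte markers had -0.74 at 0.805 (5 of 9 lower and 1 higher) and dopamine neuron genes -0.28 at 2.83 (8 of 23 lower and 5 higher). The percentiles were 9.63 for Ret and GDNF-family signalling, 11.8 for LXR, 72.8 for retinoic acid receptor and 3.55 for PPAR targets, 57.9 for the proteasome, 75.1 for the unfolded protein response and 47.6 for cycling progenitor markers. Other neuron types and oligodendrocyte, microglia and mesenchymal and vascular markers had at most 3 members above the minimum and no percentile.

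The largest changes were ranked on the log2(RPKM + 1) scale, which shrinks the folds of low genes. On it the largest rise was in Sct, secretin, with no read in the scrambled library (at least 18.4-fold higher), followed by Atf3 (0.471 and 23.0 RPKM). Further genes among the 10 largest rises, besides Fos, Fosb and Nr4a1, were the histone gene Hist1h4i and Dnajb3, with no read in the scrambled library (at least 6.69-fold and at least 16.4-fold higher), Rrad (1.54 and 36.9 RPKM) and Usp2 (0.711 and 21.9). S100a13 had 1 read in the scrambled library (ratio 55.8, 9.71 to 2232). The largest falls were Elovl1, with no read in the shNurr1 library (ratio at most 0.0242), Fbxo16 (40.9 and 2.25 RPKM) and Wdr92 (14.2 and 0.189). Further falls were Mitd1 (20.54 and 0.846), Snx32 (58.8 and 4.32), Lrrc3b (28.4 and 1.84) and Oprl1 (25.6 and 1.83). Yipf2, Ypel4 and Mfsd3 had 2, 3 and 3 reads in the shNurr1 library (ratios 0.0175, 0.00209 to 0.0652; 0.0378, 0.00758 to 0.116; and 0.0225, 0.00457 to 0.0678).

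Changes in the shNurr1 library were also set beside those of added Nurr1 and of bexarotene. Across 10174 genes, Pearson's r between the log2 changes of shNurr1 against scrambled and of synuclein plus Nurr1 against synuclein was 0.0039 and Spearman's rho 0.0169. With those of bexarotene against DMSO it was 0.0849 and rho 0.118 over 10259 genes, and 0.184 and 0.209 over the 4753 with a mean of at least 10 RPKM. Nr4a2 itself was only slightly lower in the shNurr1 library (ratio 0.838), so these relations say little about loss of Nurr1. Genes are not independent replicates, the cultures differ in age and sorting, and these 2 relations carry no p-value.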

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

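The tests of the dopamine neuron genes, of the 10 highest genes, of each pair of lists after the length trend was removed, of a difference like that between RFP1 and RFP2 and of the changes going back against each RFP set were chosen only after the result was seen. In 5 of 82 named genes, 1 RFP library lay far from the other 4 in a test that flags about 1 in 20 groups by chance. Aldoc was at 490 RPKM in RFP replicate 2_3 (381 to 405 in the others) and Cyc1 at 52.9 in the same library (40.1 to 43.7). Fdps was at 435 RPKM in RFP replicate 2_1 (350.2 to 372) and Gcg at 8.16 there (12.0 to 13.47). Hbb-y was at 2.91 RPKM in RFP replicate 1_1 (8.25 to 9.88).

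Of 20 dopamine neuron genes 9 were lower with synuclein, 2 were higher and 9 did not pass, and the set call was lost with an estimated correlation (camera adjusted p = 0.051). Shallower RFP libraries did not account for this, since 8 of the 9 lower genes stayed so after all libraries were thinned to equal depth, and a difference between RFP1 and RFP2 libraries did not, since all 9 were called against each set alone. An even loss of dopamine neurons would lower their genes alike, but the log2 fall of Slc6a3 exceeded that of Th by 1.007 (SE 0.117). Sorted DMSO cells exceeded unsorted RFP cultures by similar factors for both, 10.7-fold and 11.8-fold. At the highest factors, Dlk1 (19.8-fold) rose and Chrna6 (14.6-fold) fell. Slc10a4 (36.5-fold), Gch1 (20.1-fold) and Chrnb3 (19.5-fold) did not pass, with log2 changes of -0.45, -0.28 and -0.23. The factors mix sorting with kit, culture time and virus. The difference between the falls argues against an even loss of neurons as the whole cause. It cannot speak to a loss of only some dopamine neurons, which could lower their genes unequally. A lower level per neuron remains a hypothesis, and a partial loss of neurons was not measured.

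With bexarotene, oxidative phosphorylation, ribosome and proteasome genes were called higher, but with an estimated correlation only the cytosolic ribosome was (camera adjusted p = 0.075, 0.099 and 0.099 for oxidative phosphorylation, the mitochondrial ribosome and the proteasome). Of the 4 lists, 2 stayed above almost all matched random lists once the length trend was removed, oxidative phosphorylation and the mitochondrial ribosome, with a lower percentile of 98.9, which argues against length as the whole cause. For the cytosolic ribosome and the proteasome the higher percentile was 80.4 while camera, which compares with all genes, still called the cytosolic ribosome. The cytosolic ribosome lay at percentile 47.9, so it stood no higher than genes matched on length and level. Length and bexarotene cannot be told apart for these 2 lists. The share of reads in the 10 highest genes would shift unscaled values by only 0.00736 log2 units, and TMM scaling already allows for such a shift. Without bexarotene replicate 1 the medians kept at least 0.993 of their size. Neither accounts for the pattern. Sets of libraries that differ as RFP1 and RFP2 do stay open, because the same lists lay at percentile 0.51 or below between them with length removed, although by medians (-0.13 and -0.13) nearer 0 than the 0.41 and 0.25 with bexarotene.

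The synuclein changes that went back with added Nurr1 had a covariance of -0.0504, below the lowest of 100 simulations of shared synuclein libraries (-0.00956). With each RFP set alone the covariance nearer 0 was -0.0404, against a lowest simulated value of -0.00756, and 80.3% of the covariance was left without the length trend. These values argue against the spread within the shared libraries, the RFP sets and length as the whole cause. A deviation common to all synuclein libraries would also give a negative covariance. The simulations held only the spread within groups, so it was not tested. A response to Nurr1 remains a hypothesis, since differences in virus dose between the groups were not tested.

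Among 56 splits of the RFP and synuclein libraries, 1 called as many genes as the real groups, which was the real split; the highest other called 461. For synuclein plus Nurr1 it was again 1 of 56, with 1571 as the highest other. In both comparisons that highest other split set the RFP1 libraries against the RFP2 and treated libraries together. The direct comparison and bexarotene allow 10 splits each, of which the real 1 called the most (highest others 1 and 0), and 10 splits are too few to exclude a chance split.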

How the results depend on the processing

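Thinning, edgeR on implied reads, and list tests against each RFP set, without Nr4a2, with a block, without length or without bexarotene replicate 1 were tests chosen only after the result was seen. Over all settings, calls and directions of the named genes were the same in 1276 of 1296 gene and setting pairs for synuclein, 685 of 717 for synuclein plus Nurr1, 854 of 864 for the direct comparison and 425 of 429 for bexarotene. Genes without a call changed sign in 3 pairs: Ddc with synuclein plus Nurr1 when thinned (0.0024), Slc18a2 there against RFP2 only (-0.026) and Slc18a2 without bexarotene replicate 3 (6.4e-05). Without bexarotene replicate 1, Slc18a2 fell, by -0.17, and Ddc was called lower. The count of changed genes, 4255 with synuclein, ranged from 2465 to 4314 as libraries were left out and was 6399 against RFP2. The 3529 with synuclein plus Nurr1 ranged from 2059 to 3906, and were 6165 with library weights, 5863 against RFP1 and 5495 against RFP2. The 6397 of the direct comparison became 2131 in one fit of all 11 libraries and 2337 when thinned. The 8765 with bexarotene ranged from 8150 to 9187 as libraries were left out and from 7597 to 9847 over all settings. For shNurr1, 1104 became 3110 from 1 RPKM and 255 from 50 RPKM. The causes were not tested.

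Lists past the threshold numbered 12, 4, 9 and 4. With an estimated correlation they were 2, 2, 1 and 1, and with fry 12, 15 and 16 in the last 3. Against RFP1 or RFP2 alone 7 lists passed with synuclein plus Nurr1. In genes of at least 10 RPKM, the covariance of the 2 comparisons against RFP was 0.108, and r of shNurr1 was -0.0051 with added Nurr1 and 0.184 with bexarotene.

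The replicate numbers gave no clear sign that libraries were paired. Correlations of same-numbered libraries ran from -0.0833 to 0.0994, and 1 of 3, 0 of 3, 1 of 3 and 2 of 3 libraries correlated best with their own number. For bexarotene the 3 same-number correlations were all positive (0.0162 to 0.0633), so pairing there is not excluded. With a replicate block 3194, 2587, 6118 and 9017 genes were called, and the same numbers of lists.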

Other observations

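The genes in this part were chosen, and the comparison of RFP1 with RFP2 was made, only after the result was seen. In the sorted cells, direct targets of the liver X receptor, a retinoid X receptor partner, were called in both directions with bexarotene. That is no sign of a response of this list, since 66.4% of all tested genes were called and the list was not (camera adjusted p = 0.853). Abcg1, a cholesterol exporter, rose from 20.1 ± 0.0755 to 31.3 ± 0.786 RPKM (n = 3 each; log2 change 0.61; edgeR adjusted p = 6.5e-09) and Srebf1 from 5.70 ± 0.351 to 7.86 ± 0.00592 (0.44; edgeR adjusted p = 4.8e-05), while Scd1, a fatty acid desaturase, fell from 18.1 ± 0.152 to 12.8 ± 0.514 (-0.53; edgeR adjusted p = 3.1e-07). Abca1 did not pass (edgeR adjusted p = 0.112), nor did the retinoic acid receptor targets Rarb (edgeR adjusted p = 0.650) and Cyp26b1 (edgeR adjusted p = 0.0943). Of 9 retinoic acid receptor targets tested, 4 nevertheless rose and 1 fell.

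Between the RFP sets, 693 genes were higher and 902 lower in RFP2 than in RFP1 of 11839 tested with limma. Oxidative phosphorylation had a median of -0.36 (camera adjusted p = 6.0e-14), the mitochondrial ribosome -0.28 (camera adjusted p = 4.8e-08), the cytosolic ribosome -0.28 (camera adjusted p = 2.9e-04) and the proteasome -0.26 (camera adjusted p = 3.4e-06), and dopamine neuron genes 0.07 (camera adjusted p = 0.243). The change with transcript length had a Spearman's rho of 0.392 between the RFP sets, -0.265 for synuclein, -0.0454 for synuclein plus Nurr1, 0.272 for the direct comparison and -0.0376 for shNurr1.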
